A study of Danio rerio with 25 samples.

How the data were processed

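Total RNA of whole zebrafish larvae was labelled with Cy3 and hybridised to Agilent miRNA arrays, 100 ng per array, per the labels' protocols. Spot values were extracted with Agilent Feature Extraction 10.7.3.1, per the file headers. Each scanner file holds spot intensity on a linear scale, as a mean signal, a local background and a background-subtracted signal, not normalized between arrays, per the file headers. The deposited series value table holds the background-subtracted intensity of the same arrays, equal to the scanner files within 0.495% on all 25 arrays, so its scale and direction are settled. The authors also deposited a table of quantile-normalized log2 values for 172 miRNAs, which holds all miRNAs tested here and correlated at 0.999 with quantile-normalized signal without background subtraction. The filter behind that table is not given in the sources used here. The submitters' processing notes name limma and RMA, without versions.

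Each array has 10555 spots, of which 9840 are miRNA spots of 521 probes for 246 miRNAs. Spots carrying an outlier mark, 2.64% to 10.8% per array, were left out, and 0 spots were saturated. The mean signal was corrected with normexp fitted on all spots, control spots were then dropped, arrays were quantile normalized, spots of a probe were averaged on the log2 scale and the probes of a miRNA, 2 for 222 of them, were joined by median polish. A miRNA counted as detected on an array when at least 0.5 of its spots were well above background, and it was tested when detected on at least 2 arrays of at least 1 group. Of the rest, 91 miRNAs were detected on 0 arrays. In the LPS time average the probes of 41 of the tested miRNAs differed in sign. The share of spots well above background ran from 20.6% to 59.7%.

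The tests used limma 3.58.1 in R 4.3.3: a means model over all 9 groups, moderated statistics, two-sided, with Benjamini-Hochberg adjustment over miRNAs and a threshold of 0.05. The submitters' notes name these tools, and the groups of 2 arrays share the spread of the others. LPS and PGN were each compared with control at 1, 2 and 12 h and averaged over times, with each other, and controls over time, 16 comparisons in all. miRNA lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists and the 8 comparisons of a stimulus with control, and separately for the other kinds of comparison. The lists were inflammation-responsive, leukocyte, muscle, neural, sensory, epithelial, digestive organ, vascular and smooth muscle, cartilage and connective tissue, miR-17-92, let-7, Hox cluster, miR-430, miR-15/16, miR-23/24/27, miR-30 and star strands. The erythroid, miR-29 and miR-99/100 lists had 1, 0 and 2 tested members and gave no test. The lists overlap in part, since star strands of a family on another list belong to both.

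The miRNAs named are those past the threshold, up to 10 risen and 10 fallen; with fewer than 5, the 5 with the smallest p in a comparison of a stimulus with control; miR-146a, miR-146b, miR-155, miR-21, miR-223 and miR-142 in every such comparison; and up to 4 members of each list past its threshold. These rules, the comparisons and the lists were fixed before the data were examined. Other normalizations, filters, summaries, blocks for slide and replicate number, and omission of each array in turn were 12 settings fixed at the same time, beside the omissions. After the data were examined, 11 further settings and 3 further comparisons were added, and their results stand in the closing section, apart from the values with array brightness given beside the lists and miR-223.

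The files give 4 slides and 2 scan days, and slide 4 held no control array. The slide was tested as a fixed and as a random block. The fit was tested on simulated data made from the real means and the real residual columns of the tested miRNAs, with the columns shuffled between arrays. In 100 such data sets with nothing changed, camera at the preset correlation called at least 1 list in 69 and at least 6 lists in 12, and with an estimated correlation in 0. Limma called a miRNA in at least 1 of the 8 comparisons in 16 of them. Genomic positions of probes are not printed because the file headers name one genome build while 12 of the mappings name a scaffold of another.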

Results

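Mature miRNAs were measured in whole zebrafish larvae that had been immersed in a bacterial cell wall product, to find miRNAs that respond to immune stimulation. Larvae 72 h after fertilization were kept for 1 h in 200 µg/ml lipopolysaccharide (LPS, from the outer membrane of Salmonella) or peptidoglycan (PGN, the cell wall polymer of Staphylococcus), returned to fresh medium and sampled 1, 2 or 12 h later beside untreated larvae. Each array held RNA of 12 pooled larvae. LPS and PGN had 3 arrays at each time, and the controls had 2 arrays at 1 h, 3 at 2 h and 2 at 12 h, 25 arrays in all. Of 246 miRNAs on the array, those detected on at least 2 arrays of a group were tested, and 113 were not. Array brightness differed widely: the 75th percentile of total signal ran from 21.7 to 512, and the dimmest array detected 51 miRNAs. The dimmest arrays were replicate 2 of LPS at 1 h, replicate 2 of PGN at 1 h and replicate 3 of the controls at 12 h. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these samples, and technical spread is not excluded.

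The brightness of an array moved with many miRNAs at once. The first principal component of the tested miRNAs over all arrays held 67.6% of the variance between arrays. Its score correlated with log2 brightness across 25 arrays (Pearson r 0.875, Spearman rho 0.816, permutation p 1e-05 for each, the smallest the permutations can give, adjusted p 2.33e-05 and 3.5e-05 over 7 relations), and r was 0.828 without the 2 arrays of most extreme brightness. Within slides 1 to 4 r was 0.634, 0.966, 0.960 and 0.979 (permutation p 0.207, 0.0528, 0.00218 and 0.00417) and rho 0.486, 0.486, 0.929 and 0.943 (permutation p 0.356, 0.356, 0.00675 and 0.0167).

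**Figure D1:**
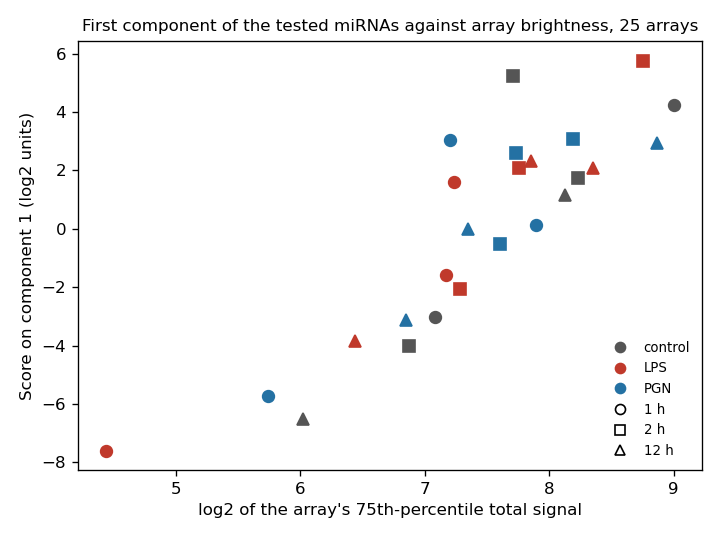
Each point is 1 of 25 arrays, with the log2 of its 75th-percentile total signal on the x axis and its score on the first component of the tested miRNAs on the y axis, in log2 units. Colour gives the treatment and shape the time, and the points rise together (Pearson r 0.875).

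Several miRNAs known from inflammation and white blood cells were at or below the limit of these arrays. The probes for miR-155, a regulator of lymphocyte and macrophage activation, miR-146b, miR-142a-5p, miR-142b-5p and the lymphocyte miRNA miR-150 were well above background on 0 of 25 arrays. miR-146a, a feedback inhibitor of Toll-like receptor signalling, was detected on 1 array, and miR-142a-3p, a miRNA of blood cells, on 6, namely 2 control, 2 LPS and 2 PGN arrays. None of these was tested. miR-21, induced in many inflammatory settings, was detected on 24 arrays and miR-223, a miRNA of neutrophils and macrophages, on 25.

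LPS against control was compared at each time and as the average over times. No miRNA passed the test in any of these 4 comparisons. At 1 h miR-223 averaged 6.12 ± 1.06 (SD, n = 3) log2 units in LPS larvae and 5.32 ± 0.68 (SD, n = 2) in controls, a log2 difference of 0.80 with a 95% interval from −0.24 to 1.84. It was 0.19 without LPS replicate 2, the dimmest array, 0.32 without control replicate 1 and 1.28 without control replicate 3, and −0.15 with array brightness as a covariate, a setting added after the data were examined. At 2 h its difference was −0.22, from −0.42 without LPS replicate 3 to 0.04 without LPS replicate 1. At 12 h it was −0.46, from −0.93 without control replicate 2 to 0.01 without control replicate 3. miR-21 differed by −0.08, 0.02 and 0.19 at 1, 2 and 12 h, and by 0.05 (−0.24 to 0.33) in the time average. With 1 array left out it ran from −0.23 to 0.17 at 1 h, from −0.06 to 0.10 at 2 h and from −0.10 to 0.49 at 12 h, the last 2 values without control replicates 3 and 2. Its average ran from −0.05 to 0.14, without the same control arrays at 12 h.

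The 5 miRNAs with the smallest p at 1 h of LPS were the muscle miRNA miR-133b (0.44), the pancreatic miR-217 (−0.48), miR-363 (−0.54), miR-181a, which acts in lymphocyte development (0.52), and miR-457a (−0.64), each with a limma adjusted p of 0.835. Without control replicate 1 the 5 were at 0.20, −0.26, −0.31, 0.17 and −0.24, and without control replicate 3 at 0.68, −0.69, −0.78, 0.87 and −1.04. Of the 3 LPS arrays, 1 detected miR-217 and 2 detected miR-363 and miR-457a. At 2 h they were miR-430b (−0.36), the neural miR-138 (0.35), miR-430j (−0.28), let-7c (−0.30) and the epithelial miR-141 (0.36), with a limma adjusted p of 0.996. Without control replicate 1 miR-430b was at −0.59, miR-138 at 0.48, miR-430j at −0.48 and let-7c at −0.65, and without control replicate 3 miR-138 was at 0.23, let-7c at −0.12 and miR-141 at 0.18. miR-430b was at −0.20 without control replicate 2 and miR-430j at −0.16 without LPS replicate 2. miR-138 and miR-141 were detected on 2 of 3 control arrays. At 12 h they were miR-99 (−0.63), miR-10d* (−0.69), miR-730 (−0.94), miR-100 (−0.55) and the smooth muscle miR-143 (0.37), with a limma adjusted p of 0.935. Without control replicate 3 miR-99, miR-10d*, miR-100 and miR-143 were at −0.35, −0.35, −0.24 and 0.21, without control replicate 2 miR-10d* and miR-100 were at −1.04 and −0.86, and without LPS replicate 1 miR-730 was at −0.60. miR-10d*, miR-730 and miR-143 were detected on 1 of 3 LPS and 1 of 2 control arrays, so that most of their values were not well above background. In the time average they were let-7c (−0.35 ± 0.15 SE), miR-196a (−0.27), miR-181a (0.32), miR-99 (−0.36) and miR-363 (−0.30), with a limma adjusted p of 0.992. There miR-181a was at 0.20 without control replicate 1 at 1 h, and miR-363 at −0.19 without control replicate 2 at 12 h. By limma, 0 miRNAs passed an adjusted p of 0.05 at each time and in the average, and 0, 0, 0 and 2 had an unadjusted p under 0.05, where 6.65 would be expected by chance. miRNAs vary together, so such counts move widely: 1 random regrouping of the LPS and control arrays within times gave 73 in the average. The model leaves the component shared by many miRNAs in the spread, so the shortfall does not speak against a response. The 95% interval spanned 1.57-fold either way for the median miRNA at 1 h and 12 h and 1.29-fold in the average. It lay within a 2-fold change for 79, 110, 84 and 131 of the tested miRNAs. Only 45 of the tested miRNAs were detected on all arrays. For miRNAs not well above background, here and in such counts below, a narrow interval does not exclude a larger change in abundance.

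**Figure D2:**
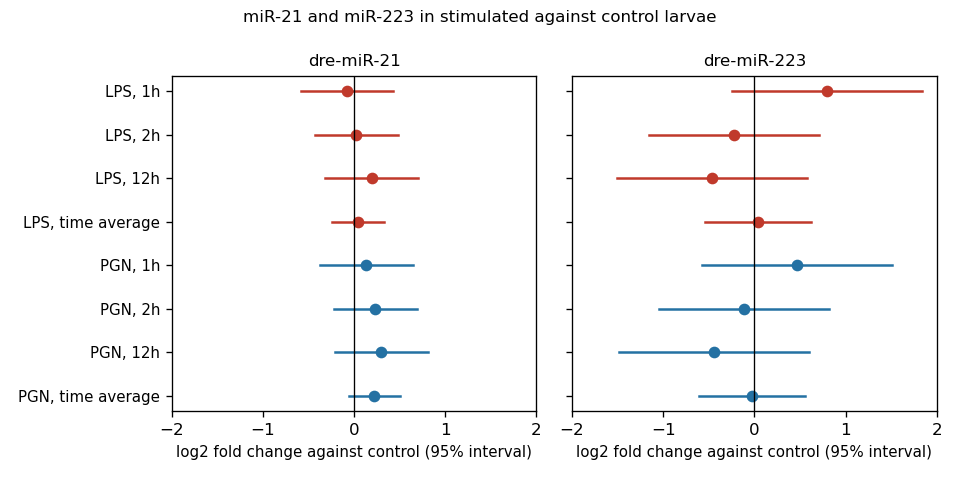
Log2 fold changes of miR-21 and miR-223 against control on the x axis, as points with 95% intervals, for LPS (red) and PGN (blue) at each time and as the time average (y axis). Every interval includes 0, and those of miR-223 are the wider ones, from −0.24 to 1.84 for LPS at 1 h.

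PGN against control likewise gave no miRNA past the test at 1, 2 or 12 h or in the time average. miR-21 differed by 0.14, 0.23 and 0.30 at 1, 2 and 12 h and by 0.22 (−0.06 to 0.51) in the average. With 1 array left out it ran from −0.02 to 0.34 at 1 h, from 0.11 to 0.31 at 2 h, and from 0.01 (without control replicate 3) to 0.59 (without control replicate 2) at 12 h. Its average ran from 0.13 to 0.32, without the same control arrays at 12 h. miR-223 differed by 0.47, −0.12 and −0.44, and by −0.03 in the average. The value at 1 h was −0.01 without control replicate 1, 0.16 without PGN replicate 2 and 0.95 without control replicate 3, and −0.12 with array brightness as a covariate. With 1 array left out it ran from −0.26 to 0.08 at 2 h, from −0.91 (without control replicate 2) to 0.03 (without control replicate 3) at 12 h, and from −0.19 to 0.13 in the average. miR-192, a miRNA of liver, gut and kidney, was 0.39 ± 0.22 (SE) higher in the mean at 1 h, with all 3 PGN arrays above both controls, and its limma adjusted p was 0.999. It was 0.23 without control replicate 1 and 0.55 without control replicate 3, and 2 of the 3 PGN arrays detected it.

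Beside miR-192, the smallest p at 1 h of PGN belonged to miR-217 (−0.43), miR-216b (−0.41), miR-363 (−0.41) and miR-181a (0.39). Without control replicate 3 these 4 were at −0.64, −0.67, −0.64 and 0.74. Without control replicate 1 miR-363 was at −0.17 and miR-181a at 0.04, and without PGN replicate 2 miR-217 was at −0.19 and miR-216b at −0.10. miR-217 and miR-216b were detected on 2 of 3 PGN arrays. At 2 h they belonged to miR-21, miR-730 (−0.44), miR-192 (0.17), miR-138 (0.22) and the epithelial miR-200c (0.23), with a limma adjusted p of 0.998. With 1 array left out miR-730 ran from −0.93 to −0.06 (without control replicates 1 and 3), miR-192 from 0.09 to 0.32 (without PGN replicates 3 and 2), miR-138 from 0.02 to 0.39 (without PGN replicates 1 and 2) and miR-200c from 0.15 to 0.31 (without control replicates 3 and 2). miR-730 and miR-138 were each detected on 1 of 3 PGN and 2 of 3 control arrays. At 12 h they belonged to miR-100 (−0.51), miR-99 (−0.51), miR-184 (−0.66), miR-10d* (−0.54) and miR-21, with a limma adjusted p of 0.980. Without control replicate 2 the first 4 were at −0.82, −0.79, −1.15 and −0.88, and without control replicate 3 at −0.20, −0.24, −0.17 and −0.20. miR-10d* was detected on 1 of 3 PGN and 1 of 2 control arrays. In the average they belonged to miR-730 (−0.58), miR-10d* (−0.38), miR-99 (−0.33), miR-192 (0.21) and miR-21, with a limma adjusted p of 0.995. Without control replicate 3 at 1 h miR-730 was at −0.34 and miR-10d* at −0.23. miR-10d* was detected on 2 of 9 PGN arrays, 0 of them at 1 h, so that its difference is mostly against values not well above background. By limma, 0 miRNAs passed in each of the 4 comparisons and 0 had an unadjusted p under 0.05. The 95% interval lay within a 2-fold change for 88, 112, 88 and 130 miRNAs. With the slide as a fixed block, miR-730 passed in the time average (−0.66 ± 0.14 SE, limma adjusted p 0.030). It was detected on 3 of 9 PGN arrays, 1 at each time, and on 5 of 7 control arrays, so that most of the PGN values were not well above background. On the slides that held 1 PGN and 1 control array of a time, dre-miR-730 differed by −0.83 and −0.53 at 1 h, −0.65 and −0.86 at 2 h and −0.53 and −0.91 at 12 h.

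miRNA groups fixed in advance were compared with all other miRNAs. The 4 leukocyte miRNAs tested (miR-181a, miR-181a*, miR-181c and miR-223) had a median log2 difference at 1 h of 0.43 in LPS larvae and 0.28 in PGN larvae, as a list each at a camera adjusted p of 0.0188, and each at an adjusted p of 0.942 with an estimated correlation. The mean of each of the 4 was above that of the controls in both, and 0 of them passed adjusted over the list alone. With array brightness as a covariate the medians were −0.0928 and −0.0865. The within-slide medians were 0.51 for LPS on slide 1 and 0.65 and −0.05 for PGN on slides 1 and 3. The LPS call was also lost without replicate 1 of the controls at 1 h (median 0.12, camera adjusted p 0.431) or replicate 2 of LPS at 1 h (0.28, 0.0935), and the median was 0.73 without replicate 3 of the controls. The PGN call was lost without replicate 1 of the controls (−0.07, camera adjusted p 0.891) or PGN replicates 1 (0.34, 0.127) or 2 (0.22, 0.306), and the median was 0.62 without replicate 3 of the controls.

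At 1 h of LPS the miR-15/16 family, 7 members, had a median of −0.44 (camera adjusted p 0.0367, and adjusted p 0.942 with an estimated correlation), among them miR-457a (−0.64), miR-16b (−0.36), miR-15b (−0.62) and miR-16c (−0.48). With array brightness as a covariate its median was 0.0675. With 1 array left out miR-457a ran from −1.04 to −0.24 and miR-16b from −0.49 to −0.16. Likewise miR-15b ran from −1.16 to −0.08 and miR-16c from −0.76 to −0.11. At 2 h of LPS the 4 members of miR-430, the family that clears maternal messages in the early embryo, had a median of −0.27 (camera adjusted p 0.0165, and adjusted p 0.942 with an estimated correlation), namely miR-430b (−0.36), miR-430j (−0.28), miR-430a (−0.26) and miR-430c (−0.04). The 6 let-7 members, a family that accumulates with differentiation, had a median of −0.25 at 2 h (camera adjusted p 0.0188; let-7a −0.25, let-7d −0.24 and let-7b −0.43) and of −0.25 in the LPS time average (camera adjusted p 0.0188; let-7a −0.28, let-7g −0.24 and let-7b −0.27). Both had a camera adjusted p of 0.942 with an estimated correlation. With brightness as a covariate the miR-430 median was −0.24 (camera adjusted p 0.154) and those of let-7 −0.24 (0.0407) at 2 h and −0.20 (0.0910) in the average. With the slide as a fixed block the medians of the 4 calls were −0.47, −0.27, −0.19 and −0.23 and those of the leukocyte list 0.35 and 0.16, and the camera adjusted p of all 6 lay between 0.0701 and 0.144. Of these calls, none held up to leaving out every array in turn. The miR-15/16 call was lost without replicate 1 of the controls at 1 h (−0.24, camera adjusted p 0.647) or LPS replicates 1 (−0.61, 0.0600), 2 (−0.17, 0.117) or 3 (−0.55, 0.0880). The let-7 call at 2 h was lost without control replicates 1 (−0.43, camera adjusted p 0.0517), 2 (−0.11, 0.182) or 3 (−0.13, 0.219) or LPS replicates 1 (−0.17, 0.0792), 2 (−0.20, 0.270) or 3 (−0.29, 0.140). The miR-430 call was lost without control replicates 2 (−0.14, camera adjusted p 0.160) or 3 (−0.18, 0.0998) or LPS replicates 1 (−0.21, 0.120) or 2 (−0.17, 0.176), and its median was −0.48 without control replicate 1 and −0.43 without LPS replicate 3. The let-7 call in the average was lost without replicate 1 of the controls at 1 h (−0.25, camera adjusted p 0.0911), replicate 2 of the controls at 12 h (−0.14, 0.180), LPS replicate 3 at 1 h (−0.19, 0.0815) or LPS replicate 2 at 2 h (−0.25, 0.0613). On slide 1 the miR-15/16 median at 1 h was −0.31. Within slides at 2 h the let-7 median was 0.16 on slide 1 and −0.54 on slide 2, and that of miR-430 was 0.00 and −0.71. No member of these lists passed adjusted over the list alone.

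The remaining groups had small median differences in the time averages of LPS and PGN. The inflammation-responsive list, which holds miR-21, miR-125, miR-132, miR-221 and miR-222 members, stood at 0.05 and −0.00. Muscle miRNAs stood at 0.05 and 0.04, neural at 0.05 and 0.05, sensory at 0.01 and 0.04, epithelial at 0.03 and 0.05 and digestive organ miRNAs at −0.10 and −0.04. Vascular and smooth muscle miRNAs stood at 0.07 and 0.04, cartilage and connective tissue at 0.11 and 0.08, leukocyte at 0.11 and 0.03, miR-15/16 at −0.10 and −0.01 and miR-430 at −0.14 and −0.05. The miR-17-92 group stood at −0.04 and −0.01, Hox cluster miRNAs at −0.05 and −0.07, miR-23/24/27 at −0.04 and 0.02, miR-30 at −0.05 and 0.03, and star strands at −0.05 and −0.03. For PGN the let-7 median was −0.11, with a camera adjusted p of 0.150. The other lists had camera adjusted p from 0.315 to 0.906 for LPS and from 0.269 to 0.906 for PGN.

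LPS was compared with PGN directly at each time and as an average. The miRNA with the smallest p was miR-16b at 1 h, miR-196a at 2 h and in the average, and miR-10a at 12 h. By limma, 0 miRNAs passed at 1, 2 or 12 h or in the average, 0 had an unadjusted p under 0.05, and the smallest adjusted p was 0.992, 0.991, 0.999 and 0.993. The 95% interval lay within a 2-fold difference between the stimuli for 100, 116 and 116 miRNAs at the 3 times. In the average it did so for all tested miRNAs, among them miR-301b, which was detected on 0 PGN arrays. A 2-fold difference is not excluded for such miRNAs. The miR-430 list was lower in LPS than in PGN at 2 h (median −0.27, and −0.26 at a camera adjusted p of 0.0516 with brightness as a covariate; miR-430j −0.25, miR-430b −0.30, miR-430a −0.28 and miR-430c −0.12; camera adjusted p 0.00552), and with an estimated correlation the camera adjusted p was 0.724. With the slide as a fixed block this call was lost (median −0.14, camera adjusted p 0.643), and within slides 2 and 4 the median was −0.20 and 0.03. The call was lost without LPS replicates 1 (−0.21, camera adjusted p 0.210) or 2 (−0.20, 0.276) or PGN replicates 2 (−0.13, 0.442) or 3 (−0.27, 0.0788), and the median was −0.43 without LPS replicate 3.

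Across miRNAs, which are not independent replicates, the log2 differences of LPS and PGN from control correlated at 0.777, 0.676 and 0.957 at 1, 2 and 12 h and at 0.819 in the time average. Unchanged groups simulated against the same controls gave mean correlations of 0.537, 0.426, 0.534 and 0.507, and the 95% range for the average ran from −0.613 to 0.974. The simulated groups took arrays at random, so they kept no likeness between arrays of the same slide or replicate number. The covariance was 0.0506, 0.0123, 0.0767 and 0.0141, beside simulated means of 0.0827, 0.0559, 0.0787 and 0.0238. With each stimulus given its own part of the controls, in 24 ways, the correlation in the average had a mean of −0.130 and ran from −0.811 to 0.729.

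Untreated larvae were compared over time, since they aged during the experiment. From 1 h to 12 h the miR-430 family had a median log2 difference of −0.62 (camera adjusted p 0.000515, and adjusted p 0.667 with an estimated correlation). miR-430j was at −0.73, miR-430b at −0.68, miR-430a at −0.57 and miR-430c at −0.55, each lower on both 12 h arrays than on both 1 h arrays, as groups of 2 often are by chance. Over all times miR-430c was detected on 4 control arrays, against 7 for each other member, so part of its values were not well above background. The miR-17-92 group, associated with cell proliferation, had a median of −0.48 (camera adjusted p 0.00200, and adjusted p 0.740 with an estimated correlation). Of its 14 members 1 was higher, and the rest were lower in the mean, among them miR-17a at −0.54, miR-18c at −0.70, miR-363 at −0.48 and miR-20b at −0.41. miR-192 was 4.92 ± 0.22 (SD, n = 2) log2 units at 1 h and 5.80 ± 0.18 (SD, n = 2) at 12 h.

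Adjusted over the list alone 1 miR-430 member passed and 0 of miR-17-92. With array brightness as a covariate the medians were −0.73 and −0.22. With the slide as a block they were −0.76 and −0.37, and on slide 3, which held 1 array of each time, −0.90 and −0.59. The miR-430 call was lost without replicate 3 of the controls at 1 h (−0.48, camera adjusted p 0.137) or replicate 2 at 12 h (−0.72, 0.124). The miR-17-92 call was lost without replicate 1 at 1 h (−0.20, camera adjusted p 0.187), and its median was −0.11 without replicate 3 at 12 h, −0.78 without replicate 3 at 1 h and −0.92 without replicate 2 at 12 h. By limma without a replicate block, 0 miRNAs passed in this comparison, 3 had an unadjusted p under 0.05, and miR-192 had the smallest adjusted p (0.237). With the replicate block, a setting fixed beforehand, miR-192 and the miR-430 members passed, as given in the closing part on processing. The miR-430 median was then −0.83 (camera adjusted p 1.19e-08). These control groups shared only replicate number 3 (residual r 0.902), so the block rests on little pairing here. From 1 h to 2 h limma gave 0 miRNAs past the threshold, 0 with an unadjusted p under 0.05, and a smallest adjusted p of 0.990. The 95% interval lay within a 2-fold change for 69 miRNAs from 1 h to 12 h and for 110 from 1 h to 2 h.

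**Figure D3:**
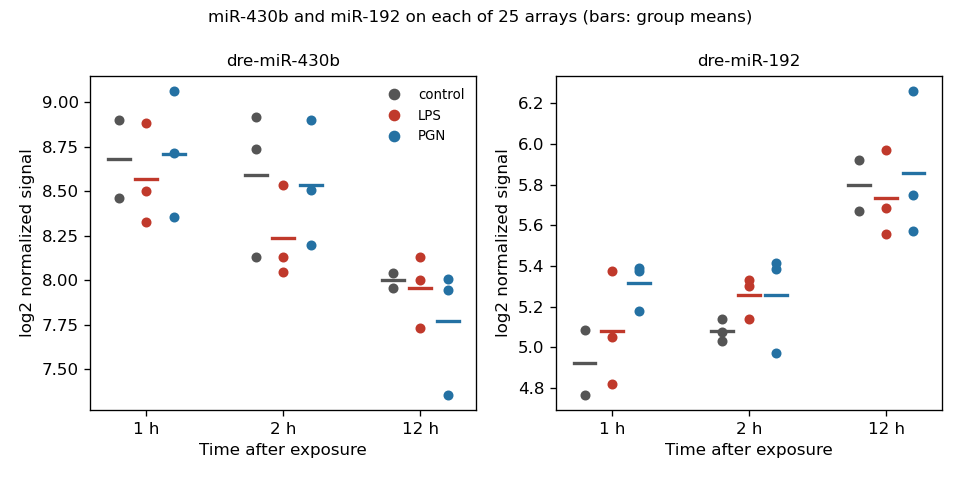
Log2 normalized signal (y axis) of miR-430b and miR-192 on each of 25 arrays, by time after exposure (x axis), in control, LPS and PGN larvae, with bars at the group means. The mean of miR-192 in control larvae is 4.92 at 1 h and 5.80 at 12 h.

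Whether the response itself changed between 1 h and 12 h was tested as a difference of differences. The smallest p belonged to miR-223 for LPS and to miR-217 for PGN. By limma, 0 miRNAs passed for LPS and 0 for PGN, 0 had an unadjusted p under 0.05, and the smallest adjusted p was 0.667 and 0.962. The 95% interval lay within a 2-fold difference for 37 and 49 miRNAs. In simulated data with 40 of the tested miRNAs changed, limma recovered 57.1% of 2-fold changes and 95.2% of 4-fold changes for LPS at 1 h, and 94.2% of 2-fold changes for the LPS time average. Of 1.41-fold changes, nearer the size of the differences named here, it recovered 4.62% for LPS at 1 h and 48.1% for the average. For the average, the change was added to LPS larvae at 1, 2 and 12 h alike. A change at a single time would be diluted in the average, so these shares do not cover it. The changes were added to normalized values of miRNAs drawn at random, so losses near background or in normalization are not part of these shares. A response of fewer miRNAs was not simulated.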

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

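All tests in this part were chosen only after the results were seen.

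Outside the miRNAs tested, 22 others were detected on at least 1 array, and 7 of these on 0 control arrays but on some stimulated ones. miR-219, a miRNA of the nervous system, was detected on 4 arrays (2 LPS and 2 PGN). miR-101b, miR-107b and miR-182* were each detected on 2 arrays, 1 LPS and 1 PGN. miR-146a was detected on 1 PGN array, and miR-202 and miR-733 on 1 LPS array each. In the other direction, miR-128, miR-454b and miR-455 were each detected on 1 control array and on 0 stimulated arrays. Counted over all spots, the largest share well above background on any array was 50% for miR-219, miR-101b, miR-107b, miR-182* and miR-146a. It was 47.5% for miR-733 and 55% for miR-202, so all 7 lay close to the detection cutoff of 0.5. Only 7 of the 25 arrays were controls, and whether these counts differ between groups was not tested.

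The component that separated arrays within groups went with array brightness, at r 0.875. A correction for probe GC content and length within each array removed 29.8% of the variance between arrays, against 67.6% held by the component, which argues against probe composition as the whole cause; the first component of the remainder still held 62.2%. Across miRNAs, which are not independent, loadings went with probe GC share (r −0.559, rho −0.554, permutation p 1e-05 each), so a part played by composition is not excluded. Stimulus and time held 18.3% of the component, beside 33.3% from shuffled group labels (permutation p 0.873). The shuffle took no account of replicate number, with which the score went, so it cannot exclude a part played by the treatments. Of the arrays numbered 2, those of LPS and PGN at 1 h, both among the dimmest, had the lowest scores (−7.60 and −5.73). Brightness is a candidate source, and what made arrays bright or dim, such as labelling or RNA quality, stays open. The score also went with replicate number. It ran from 1.62 to 5.76 on arrays numbered 1. On those numbered 2 it ran from −7.60 to 3.08, and on those numbered 3 from −6.52 to 0.148. Slide 1 held only arrays numbered 1, and slide 4 only arrays numbered 3. A source tied to replicate number or slide is not excluded. No biological explanation beyond stimulus and time was tested.

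All 6 list calls against control were lost when camera estimated how far members vary together between arrays (adjusted p 0.942). The mean residual correlation of members was 0.683, 0.713 and 0.719 for the leukocyte, miR-15/16 and miR-430 lists, which is consistent with members that vary together there, but 0.190 for let-7, where this stays open. With array brightness as a covariate, the leukocyte median in LPS larvae at 1 h went from 0.43 to −0.0928, which is consistent with brightness as its source. The let-7 median in the LPS time average went only from −0.25 to −0.20, with a camera adjusted p of 0.0910 and a range from 0.00132 to 0.942 over its settings, so brightness as its source is neither shown nor excluded. Whether leukocyte miRNAs respond to the stimuli stays open.

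Other splits of the same arrays were set beside these results. For comparisons of 3 arrays with 3 the 10 splits are too few for a share under 0.05: the real count was 0 and the highest other 0 for LPS and for PGN against control at 2 h, 0 and 9 for LPS against PGN at 1 h, and 0 and 0 at 2 h and at 12 h (10 of 10 as large each time, as any split is beside a count of 0). At 2 h of LPS, 4 of 10 splits gave a let-7 median as large as −0.25 (highest other −0.39) and 3 of 10 a miR-430 median as large as −0.27 (highest other −0.58), and 3 of 10 did for miR-430 in LPS against PGN (−0.27, highest other −0.42). In the time averages the real count was 0, so that 100 of 100 splits were as large by construction and the share decides nothing. The highest other count was 1 for PGN, 7 for LPS against PGN and 53 for LPS, and a split with 53 calls points to a structure of the arrays other than the groups. For let-7 in the LPS time average 5 of 100 splits gave a median as large (−0.25, highest other 0.31), so chance was not excluded.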

How the results depend on the processing

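Of the tests in this part, the settings named as added and the comparisons of all larvae over time were chosen only after the data were seen. Over the settings fixed beforehand and omissions of 1 array, 319 of 321 counts for the 16 comparisons were 0, as in the fit reported. The exceptions were 1 miRNA in the PGN time average with the slide as a fixed block (miR-730) and 5 in controls at 12 h against 1 h with the replicate block (miR-192 up, 4 miR-430 members down). With 1 array left out the counts stayed at 0 in all 16 comparisons. Same-numbered arrays did not all deviate together: 69 of 92 pairs had a residual correlation over 0.1, with a minimum of −0.760. The numbers were therefore not taken to pair the series as a whole. Nearly all pairs at or under 0.1 held an LPS or PGN array at 1 h, so pairing in other groups is not excluded. The median was 0.682 for the same number and −0.269 for others, 24 of 25 arrays correlated best with one of their own number, and all 3 pairs were over 0.1 for LPS and PGN against control at 2 h and for LPS against PGN at each time, a hint from the data only. In those comparisons the replicate block changed no call. All shared pairs were also over 0.1 for LPS and PGN against control at 12 h. The same held for controls at 2 h (r 0.889 and 0.956) and at 12 h (r 0.902, 1 pair) against 1 h. The 5 calls with the replicate block came from the last of these. The block moved none of the other 15 counts. Of the list calls against control, miR-15/16 at 1 h of LPS was lost (camera adjusted p 0.0684), and miR-17-92 at 1 h and let-7 at 12 h of PGN were gained. In controls, miR-430 (camera adjusted p 0.00389) and sensory (0.0458) were gained at 2 h against 1 h, and cartilage and connective tissue (0.0439) at 12 h. Leukocyte (0.0268 each) and miR-17-92 (0.0315 and 0.0268) were gained in the LPS and PGN responses, 12 h minus 1 h.

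Of the 11 added settings, brightness with a slide block gave 1 miRNA for PGN at 1 h and 3 in the PGN time average. For controls at 12 h against 1 h the GC correction with a replicate block gave 5, brightness with a replicate block 10, and the GC correction with a term for arrays numbered 2, tried without a rationale, 2. The first residual component as a covariate gave 16 (LPS at 1 h), 6 (LPS at 12 h), 2 (PGN at 12 h), 17 (controls at 12 h) and 24 (LPS response, 12 h minus 1 h). Components 1 and 2 gave 38, 12, 3 (LPS average), 3 (PGN at 12 h), 32, 46 and 20 (PGN response). These covariates leave the fold changes as they are and shrink the spread by construction: with shuffled groups 100 of 100 data sets gave calls, up to 94 and 103 in a comparison, and 37 and 32 of 100 gave as many as LPS at 1 h. They are no evidence of a response.

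List calls against control numbered 6. They were 3 with the 75th percentile over all probes and 3 with the series value table, 0 with miRNAs detected on all arrays (fewer tested), 0 with the slide fixed, 2 with the slide random, 0 with an estimated correlation, 2 with brightness, 2 with the GC correction, 1 with brightness and replicate block, 0 with brightness and slide block, 2 with GC and the term for number 2, 0 with residual component 1 and 3 with components 1 and 2. With 1 array left out they ran from 0 (without LPS 2 h replicate 2) to 13 (without control 12 h replicate 3). Reversed medians were −0.0928 (leukocyte, LPS 1 h), −0.0865 (leukocyte, PGN 1 h) and 0.0675 (miR-15/16, LPS 1 h) with brightness, and −0.10 and −0.15 (leukocyte, LPS and PGN at 1 h) with brightness and slide block. The correlation of LPS with PGN in the time average went from 0.819 to 0.455 with the slide fixed. Every setting stayed within the simulated SD of 0.459, but so wide a margin does not show the correlation to be stable.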

Other observations

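The comparisons of all larvae over time, and all tests in this part, were chosen only after the data were seen, and 3 such comparisons were made: 12 h against 1 h in all larvae, the same in stimulated larvae alone, and 2 h against 1 h in all larvae. Across control, LPS and PGN larvae together, 4 miR-430 members were lower and miR-192 and miR-183 higher at 12 h (n = 8 arrays) than at 1 h (n = 8). By limma 6 miRNAs passed: miR-430b fell by 0.75 (SE 0.16, adjusted p 0.00940), miR-430j fell by 0.59 (SE 0.13, adjusted p 0.00940), miR-430a fell by 0.59 (adjusted p 0.0319) and miR-430c fell by 0.50 (adjusted p 0.0331). miR-192, of liver, gut and kidney, rose by 0.69 (SE 0.12, limma adjusted p 0.00228), and miR-183, of hair cells and retina, rose by 0.52 (SE 0.14, limma adjusted p 0.0331). All 8 arrays at 12 h lay beyond all 8 at 1 h for miR-430b, miR-430j, miR-192 and miR-183, 7 of 8 did for miR-430a and 5 of 8 for miR-430c. The members of miR-430 have closely similar sequences, so their 4 calls are not independent. Of all 25 arrays, 19 detected miR-430c and 20 detected miR-183, so part of their values were not well above background.

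Each treatment showed the same signs. The called miRNAs were chosen on the mean over these treatments, so likeness between treatments or slides is no separate evidence. Within a single treatment none of them passed (smallest limma adjusted p 0.192, in PGN larvae). miR-430b differed by −0.68 in controls, −0.62 in LPS and −0.94 in PGN larvae, and miR-192 by 0.87, 0.65 and 0.54. Within slides 1 to 4 the miR-430 median was −0.56, −0.92, −0.86 and −0.43. The miR-192 difference was 0.90, 1.14, 0.45 and 0.44, and that of miR-183 0.44, 1.34, 0.49 and 0.07. Slide 1 held 1 array at 12 h, and slide 2 held 1 array at 1 h, the dimmest of all. The largest of these differences, on slide 2, thus rest on that array at 1 h. As lists, miR-430 (median −0.59, camera adjusted p 3.5e-10, and adjusted p 0.0186 with an estimated correlation) and sensory miRNAs (median 0.50, camera adjusted p 0.0300, and adjusted p 0.473 with an estimated correlation) passed, as did miR-17-92 (median −0.14, camera adjusted p 0.0300, and adjusted p 0.591 with an estimated correlation). The miR-17-92 median was −0.30 without control 12 h replicate 2 and 0.01 without control 12 h replicate 3. In stimulated larvae alone, a part of the same arrays and so no separate evidence, limma called miR-192 (0.60) and miR-430b (−0.78), both at an adjusted p of 0.0236. At 2 h against 1 h limma called 0 miRNAs, and 0 had an unadjusted p under 0.05.

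This pattern was weighed against array brightness and slide. With brightness as a covariate 6 of the 6 miRNAs stayed past the threshold, and with the slide as a fixed block 6 of 6, which argues against either as the whole cause. With the 3 dimmest arrays left out only 1, miR-192, stayed past it; miR-430b went from −0.75 (SE 0.16) to −0.65 (SE 0.18) and miR-430c from −0.50 to −0.34. With only the arrays of the groups compared 3 of the 6 stayed past it. Leaving out 1 array kept 1 (without control 1 h replicate 3) to 6 of them, 2 without control 12 h replicate 3, and 3 without LPS 1 h replicate 2, PGN 1 h replicate 2, LPS 12 h replicate 1 or PGN 12 h replicate 1. Signs of those in the fit stayed the same in every setting, which is likely where the same arrays chose the miRNAs. With only miRNAs detected on all arrays, 2 of the 6 were in the fit. The 2 calls in stimulated larvae went to 0 with either 75th percentile scaling, the series value table, only the groups compared or brightness. They also went to 0 with the 3 dimmest arrays left out, and ran from 0 to 4 with 1 array left out. A decline of miR-430 as larvae grow older may be proposed only as a hypothesis, and the larvae's age and the time after handling cannot be separated here.

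Other splits of the arrays were also examined. They cannot exclude chance, since the comparisons were chosen after these values were seen, and 1 of 100 is the smallest share possible. For all larvae at 12 h against 1 h, 1 of 100 splits, the real one, gave as many as 6 calls (highest other 4), and for stimulated larvae 1 of 100 gave as many as 2 (highest other 0). By the size of the median, 1 of 100 splits was as large for miR-430 (−0.59, highest other −0.57) and for sensory miRNAs (0.50, highest other 0.50) in all larvae, and 1 of 100 for miR-430 (−0.56, highest other 0.53) and sensory miRNAs (0.54, highest other −0.53) in stimulated larvae, while 46 of 100 were for miR-17-92 (−0.14, highest other 0.41). By the camera p another split was smaller for sensory miRNAs in both and for miR-430 in stimulated larvae (1.01e-11 against 3.77e-11), so the real split was not the most extreme by that measure. At 2 h against 1 h the real count was 0, so that 100 of 100 splits were as large by construction and the share decides nothing, and the highest other was 33.

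miR-1 and miR-133a, singled out after their values were seen, are processed from shared primary transcripts, yet their deviations from group means went in opposite directions across 25 arrays (Pearson r −0.940, Spearman rho −0.905, permutation p 1e-05 for each, the smallest possible). Without the 2 arrays of most extreme miR-1, r was −0.939. Within slides 1 to 4 r was −0.305, −0.983, −0.948 and −0.931, so the relation was weak on slide 1. The pair was chosen for this pattern, so the p-values do not test it. Array brightness correlated with miR-1 at r 0.796 and with miR-133a at −0.887. The 2 miRNAs thus moved in opposite directions with brightness, and no difference in their processing can be inferred. With miR-1, miR-133a*, the other strand of the miR-133a hairpin, had r 0.857 and the muscle miRNA miR-499 0.980. Probe GC was 26.8% for miR-1, 60.7% for miR-133a, 33.3% for miR-133a* and 37.9% for miR-499.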
